A study of Homo sapiens with 12 samples.

How the data were processed

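The 12 libraries were made from THP-1 cells, a human monocytic leukemia line that becomes adherent and macrophage-like under the phorbol ester PMA. Per the labels, cells were treated with PMA at 100 ng/ml for 48 h, polyadenylated RNA was enriched on oligo(dT) beads, and libraries for m7G meRIP-seq (immunoprecipitation of RNA fragments carrying 7-methylguanosine) were sequenced on a DNBSEQ-T7. Groups came from the library names: NC is the control and KD the knockdown with a short hairpin against METTL1, IP is the immunoprecipitate and IN was taken as its input. Each of the 4 groups (NC IN, NC IP, KD IN and KD IP) held 3 libraries.

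The authors deposited a single table of 9958 peaks. Per the labels, reads were trimmed with fastp 0.23.4 and the genome build was GRCh38. The aligner, the peak caller and the read counter were not given in the sources used here. Peaks were named for KD (5008) or NC (4950), so calls are given per group and not per library. How they were made was not stated, and the part of the numbering that is absent from the table was not analysed here. The deposited counts are raw reads per peak and library, whole numbers without normalization. The deposited fold enrichment is a ratio of IP over input per peak, and the deposited score equals it. The authors also deposited p values and adjusted p values for each peak call, a log2 change in enrichment between the groups, which the counts showed to be KD over NC, and p values for that change. The deposited length is in bases.

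Peaks were assigned to genes by overlap with RefSeq gene bodies of the same build. Names were given by overlap whatever the strand, since the reference gave no gene strand, so a peak can lie opposite to the named gene. The reference gave no exons, so untranslated regions and coding sequence were not separated, and position was described in 10 equal parts of the gene body. Of the peaks, 9165 (92.0%) overlapped 1 protein-coding gene, 613 overlapped several, 51 a long non-coding RNA and 117 no gene. Genes named in the peaks numbered 4934. A peak was called shared when at least 1 base overlapped a peak of the other set.

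Reads in peak regions summed to between 907024 and 1105477 in the 6 IN libraries and between 1476384 and 1888972 in the 6 IP libraries. These sums cover peak regions alone and are not the sequencing depth. IP over input therefore measures a region against the average peak region, not against the transcriptome. Counts were fitted with edgeR 4.0.16 in R 4.3.3 after filterByExpr (minimum count 10, minimum total 15), which kept 5113 regions, with TMM scaling and a quasi-likelihood F test on 4 group means (8 residual degrees of freedom). The contrasts were the change in enrichment, (KD IP over KD IN) against (NC IP over NC IN), IP over IN in each group, and KD over NC in IN and in IP. P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and adjusted p values in the text are from edgeR unless another tool is named. Tests were two-sided. CPM values used TMM-scaled totals of the tested regions. Ratios per library in untested regions used a pseudocount of 0.5 CPM. Where a group had 0 reads, the fold was bounded with a floor of 3 counts over the group, and with 1 to 3 reads a ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

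Before the data were examined, 32 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. Besides METTL1, WDR4, RNMT and BUD23, the rule named, among regions past the threshold whose KD and NC (or IP and IN) libraries did not overlap, 1 region per gene, the 10 highest and the 10 lowest, and for each list up to 4 members with the smallest p; not every region so named is printed. Of the 32 lists, 26 had at least 3 tested regions and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation and fry beside it. The naming rule was also applied to the authors' own calls. Regions of the enrichment change that missed the threshold are named by smallest p, a choice made after it was seen that none passed. Marker lists for the HEK293 cell line, pan-leukocyte, fibroblast, surface epithelium, erythroid, lymphoid and hepatocyte genes were written after values had been seen.

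Alternatives comprised DESeq2 1.42.0, library size alone, no filter, at least 50 reads, replicate blocks, IP alone, other thresholds, stricter peaks, another overlap, other set tests and leaving out each library. Regions called in both groups, 1 region per overlapping cluster and genes with all peaks on 1 strand were added after the data had been seen. The methods were tested on simulated data made from these counts: 4-fold changes in 99 regions were recovered in 71.7% for the enrichment change, with 3.5% false calls, and 2-fold changes in 39.6%. For input, 4-fold changes were recovered in 85.6%. Of 10 simulated shifted lists 10 were recovered, with 1 false call among 10 others. Simulated regions were drawn independently and at random into lists, so correlated members and overlapping peaks of real lists were not covered. Annotation and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Exact binomial (Clopper-Pearson) 95% intervals accompany shares of peaks. Peaks and regions are not independent replicates.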

Results

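The 12 libraries measured m7G, a methylated guanosine found at mRNA caps, in tRNA and at internal sites, in PMA-treated THP-1 cells with control (NC) or METTL1 knockdown (KD), with 3 input (IN) and 3 immunoprecipitated (IP) libraries per condition. METTL1 is the catalytic subunit, with WDR4, of an m7G methyltransferase. Reads in peak regions averaged 975243 ± 73267 (SD, n = 3) in NC IN, 1044407 ± 80091 in KD IN, 1554048 ± 107410 in NC IP and 1733190 ± 195730 in KD IP. Across regions, log2 CPM of libraries correlated at r = 0.931 to 0.947 within an input group and 0.971 to 0.979 within an IP group, and at 0.84 to 0.855 between KD IN and NC IN. No peak overlapped METTL1, WDR4, RNMT or BUD23, and none of the 6 genes in the list of m7G methyltransferases and cofactors had a region, so the level of the targeted gene was not measured here.

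The peak sets address how many m7G peaks the control and the knockdown had and where. The NC set held 4950 peaks and the KD set 5008, and 1965 genes had peaks in both, 1483 in NC alone and 1486 in KD alone. Of all peaks, 38.9% overlapped a peak of the other set by at least 1 base (38.8% of KD peaks, 95% interval 37.4 to 40.1, and 39.1% of NC peaks, 37.7 to 40.5), and 29.2% did so by 50% of both peaks. Shared peaks were wider, with a median of 242 bases (quartiles 181 and 420), than peaks in 1 set, with 152 (92 and 212). Calls were given per group and not per library, so the difference of the peak numbers was not tested. The authors' adjusted p of a peak call reached 0.415, so the sets include peaks with weak calls. With each set cut to its upper 50% of peaks by the authors' fold, 20.4% overlapped a remaining peak of the other set. Cutting the other set lowers this share by itself, so it does not show that stronger peaks were shared less.

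Peaks lay at both ends of gene bodies. Of 9165 peaks in 1 protein-coding gene, 33.0% (32.1 to 34.0) lay in the first 10% of the gene from the 5 prime end and 28.8% (27.8 to 29.7) in the last 10%, against 3.0% to 9.6% in each 10% between. The first 10% held 33.3% (31.9 to 34.6) of NC peaks and 32.9% (31.5 to 34.2) of KD peaks. Positions are along the gene body with introns, so they are not transcript features. The 5 prime end is that of the strand of the peak, as the reference gave no gene strand. Peaks lay on both strands in 55 of 2374 genes with at least 2 peaks. The share at either end, which the strand cannot change, was 61.8%.

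**Figure D1:**
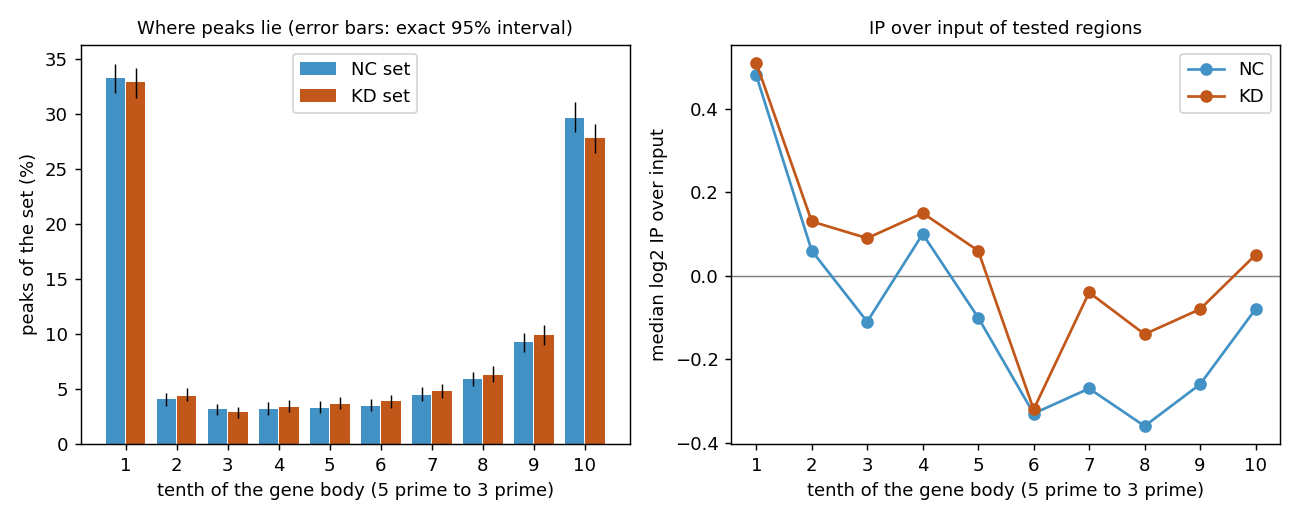
Left, percent of the peaks of the NC set (blue) and the KD set (orange) in each 10% of the gene body, with exact 95% intervals as error bars. Right, median log2 IP over input of the tested regions in each 10%, which was 0.48 in NC and 0.51 in KD in part 1 and -0.36 and -0.14 in part 8.

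IP against input asks which peak regions were enriched by the antibody more or less than the average peak region. In NC, the regions with the highest log2 IP over input had no read in the 3 input libraries: PCSK6, a proprotein convertase (chromosome 15, 101312188 to 101313077), had 41 ± 8.86 CPM (SD, n = 3) in IP, at least 36-fold higher, AJM1 was at least 10.1-fold higher, and FGF2, a fibroblast growth factor, at least 7.71-fold. The lowest were PPHLN1 (1.96 ± 0.651 CPM in IP and 28.1 ± 4.87 in IN, 14.2-fold lower) and CPVL, a serine carboxypeptidase of macrophages (12.5-fold lower). In KD, SLC17A7, a vesicular glutamate transporter (chromosome 19, 49441459 to 49442360), was at least 19.7-fold higher in IP with 19.7 ± 8.01 CPM, TMEM178A at least 16.3-fold, and KCNJ11, a potassium channel subunit, at least 13.4-fold. The lowest in KD were PIGG, of glycosylphosphatidylinositol anchor synthesis (16-fold lower), RIMS3 (8.57-fold lower) and TRAPPC2L (8.13-fold lower).

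Other regions named by the rule in NC were HIP1R, SYVN1, TNRC18, KCNAB2, TRIM13 and INTS6, at least 6-fold to 9.25-fold higher, and CBY1, PREPL, CCND2, DUS1L, IGF2BP3, NEK2, SDK2 and DMWD, 5.66-fold to 9.08-fold lower. TRIM13 lost its call without NC IP replicate 1 (log2 4.76, adjusted p = 0.12), DUS1L without NC IN replicate 2 or 3 or NC IP replicate 1 (log2 -2.48, -2.56 and -2.74), and DMWD without NC IN replicate 2 (log2 -1.93, adjusted p = 0.056). In KD they were GPT, TMEM276, ISYNA1, MAP3K12, PKP4, USP27X and HIGD1A, at least 5.91-fold to 8.41-fold higher, and DMWD, STX3, M6PR, RGS3, KDM5B, SSTR2 and UBXN11, 4.57-fold to 7.33-fold lower. Of these, RGS3 lost its call without KD IP replicate 2 (log2 -1.9, adjusted p = 0.055), KDM5B without KD IP replicate 3 (log2 -1.79, adjusted p = 0.07) and UBXN11 without any of 4 libraries (log2 -1.86 to -2.21: KD IN replicates 1 and 2, KD IP replicates 1 and 3). The log2 value also moved by over 1.5 times on the linear scale in UBXN11 and STX3 without KD IP replicate 2 (-2.88 and -3.28, from -2.16 and -2.51). It did so in DMWD without KD IN replicate 1 (-2.21, from -2.81) and in HIGD1A without KD IP replicate 1 (5.38, from 6.04).

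In NC 2389 of 5113 tested regions differed, 1161 higher and 1228 lower in IP, and in KD 2296 differed, 1200 higher and 1096 lower. Both groups called the same 815 regions higher and 902 lower, with 11 called in opposite directions, and log2 values of the groups correlated across regions at r = 0.63 (Spearman's rho 0.7), regions not being independent replicates. Every IP library lay on 1 side of every IN library in 57.8% of regions in NC and 56.6% in KD. Chance gives 10% for regions chosen without regard to IP and IN. These regions are peaks called in the same groups, so the excess may be partly built in. The split depends on the scaling: with library size alone 67.2% of called regions in NC and 63.6% in KD were higher, against 48.6% and 52.3% with TMM, and the median of all regions moved from 0.13 to 0.42 in NC and from 0.23 to 0.4 in KD.

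Regions in the first 10% of genes were more enriched. Their median log2 IP over input was 0.48 in NC and 0.51 in KD, against -0.15 and 0 elsewhere, and they were called higher in 29.1% of 1958 regions against 17.3% of 2806 in NC (odds ratio 1.96, 1.71 to 2.26; Fisher's exact p = 9.3e-22) and in 29.3% against 18.6% in KD (odds ratio 1.81, 1.58 to 2.08; Fisher's exact p = 1.4e-17). Overlapping peaks of the NC and KD sets count as separate regions here, so these intervals and p values overstate the evidence. Within the regions of lowest input per kb the gap between the first 10% and the rest was -0.03 in NC and 0.03 in KD. In the middle and highest groups of input per kb it was 0.28 and 0.21, in both NC and KD. Input is also the denominator of the ratio, so these groups cannot tell whether low input coverage gives the difference.

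Many regions of chaperone, stress response and glycolysis genes were lower in IP than in input in both groups, relative to the average peak region. No list call held with an estimated correlation. Lower here means less enriched than that average and does not by itself mean a lack of enrichment. The ENO1 region given below had a deposited fold enrichment of 1.46. Of 10 regions of heat shock and chaperone genes, 7 were lower in IP in NC and 8 in KD, with none higher. HSP90AB1 (log2 -0.95 ± 0.09 SE in NC and -0.71 ± 0.08 in KD) and HSP90AA1 (-0.95 ± 0.09 and -0.66 ± 0.09), the cytosolic HSP90 chaperones, were among them. Of 18 regions of the unfolded protein and integrated stress response, 12 were lower in each group, such as ATF4, its transcription factor (-0.81 ± 0.11 and -1.05 ± 0.11), and of 16 glycolysis regions 8 in NC and 9 in KD, such as the glycolytic enzymes ENO1 (-0.93 ± 0.15 and -1.77 ± 0.15) and TPI1 (-0.81 ± 0.11 and -1.08 ± 0.11). Oxidative stress and ferroptosis regions were lower in 6 of 8 in each group.

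Adjusted over the list alone, 7, 12, 10 and 6 regions were lower in NC and 8, 12, 11 and 6 in KD for chaperones, stress response, glycolysis and oxidative stress. Camera called these 4 lists down in NC (adjusted p = 0.0025, 0.0045, 0.0045 and 0.043, in that order; 0.12, 0.41, 0.35 and 0.3 with an estimated correlation). It did so in KD as well (adjusted p = 0.00052, 1e-04, 0.00058 and 0.0065; 0.092, 0.18, 0.18 and 0.12 with an estimated correlation). In KD it also called ribosomal proteins (12 of 18 lower, adjusted p = 0.016), RNA splicing and hnRNP (19 of 41 lower, 8 higher, adjusted p = 0.016), mitochondrial respiration (5 of 10 lower, adjusted p = 0.018) and mRNA cap binding and translation initiation (8 of 14 lower, 2 higher, adjusted p = 0.048), at 0.2, 0.51, 0.47 and 0.18 with an estimated correlation. Within the cap-binding list, EIF4G1, the scaffold of the cap-binding complex, was higher in IP (log2 3.18 ± 0.24 in NC and 2.62 ± 0.23 in KD), while EIF4B was lower (-1.16 ± 0.1 and -0.98 ± 0.1). The medians of the 4 lists called in NC stayed below 0 with library size alone (-0.43, -0.34, -0.36 and -0.48). Overlapping peaks of the NC and KD sets count as separate regions in these lists, so the counts and camera p values overstate the evidence.

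The change in enrichment asks whether METTL1 knockdown altered the m7G signal of a region beyond RNA abundance, relative to the average peak region. No region passed the threshold with edgeR. Each library was scaled to its own reads in peak regions, so a change common to all regions would not be seen. The smallest p values were for EEF1A2, an elongation factor isoform of muscle and neurons (chromosome 20, 63488397 to 63489068; log2 IP over input -1.59 in NC and 1.63 in KD, change 3.22 ± 0.65 SE, adjusted p = 0.12), HAPSTR1 (1.14 ± 0.23, adjusted p = 0.12), and RPL28, a ribosomal protein (-2.91 ± 0.61, adjusted p = 0.12). The EEF1A2 region had 8 reads in KD IN and 47 in KD IP, against 470 in NC IN and 308 in NC IP. Its KD ratio therefore rests on few input reads of a transcript far lower in KD. CBY1 and FLNA, an actin crosslinker, also had an adjusted p of 0.12, but 0 reads in KD IN, so their changes were not measured. GNAS, a G protein subunit, had 0.89 ± 0.21, SRF 0.65 ± 0.16, the macrophage growth factor CSF1 -1.61 ± 0.39 and ENO1 -0.84 ± 0.21, each with an adjusted p of 0.13. With edgeR, EEF1A2 passed without KD IN replicate 1 (4.45, adjusted p = 0.039) and was 2.58 without KD IN replicate 3. HAPSTR1 passed without NC IP replicate 1 (1.35, adjusted p = 0.016 in edgeR) and RPL28 without NC IN replicate 1 (-3.52, adjusted p = 0.035).

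The edgeR count was 0 of 5113 regions, with 610 at an unadjusted p under 0.05 (256 expected by chance) and a smallest adjusted p of 0.116. DESeq2 called 12 regions, 5 higher and 7 lower in KD, edgeR without the count filter 45, and edgeR on the upper 50% of peaks by the authors' fold 40. With a block for IP and input of the same number edgeR called 16, 15 higher and 1 lower, but that pairing is not shown. At this depth 2-fold changes were recovered in 39.6% of simulated regions. Before changes were added, each simulated region had the same level in all groups and a spread typical of that level. Recovery in the real regions can therefore differ. Regions in the KD set alone had a median change of 0.49 (quartiles 0.14 and 1.19), those in the NC set alone -0.44 (-0.99 and 0) and shared regions 0.07 (-0.23 and 0.35). Among regions with over 3 reads in each group the medians of the first 2 were 0.44 and -0.41.

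Of the gene lists, camera called cytokines and acute inflammatory mediators down in enrichment change (adjusted p = 0.043; 0.63 with an estimated correlation; median -0.85 over 8 regions). These 8 regions belong to TGFB1 and CSF1 alone, none passed the threshold over all regions, and 2 passed adjusted over the list alone. The number of lists called was 0 without KD IN replicate 2, KD IP replicate 1 or 2, NC IN replicate 2 or 3, or NC IP replicate 2 or 3, and 2 without KD IN replicate 1 or NC IN replicate 1. Ribosomal proteins had a median of -0.19 over 18 regions (adjusted p = 0.054; 0.63 with an estimated correlation), and macrophage markers -0.02 over 22 regions (adjusted p = 0.83).

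The authors' own comparison, as deposited, called 78 regions of 71 genes at an adjusted p under 0.05, 35 higher and 43 lower in KD. By their log2 change the highest among regions with 1 gene were ULBP3, a ligand of the NKG2D receptor (11.07), AK3 (11.07), MAP1A (11.07), CBY1 (10.75), ISG20L2 (10.55), FBXO3 (10.33), ZNF202 (10.33), SMIM10 (10.33), MAGI3 (9.33) and PNMA8A (9.33). The lowest were SPHK1, a sphingosine kinase (-10.82), ATP2B1, a plasma membrane calcium pump (-10.82), DUSP4, a MAP kinase phosphatase (-10.67), CNP (-10.5), SEMA3D (-10.5), ZCCHC14 (-9.82), ZNF627 (-9.5), VEZT (-9.5), HIPK2 (-9.5) and YWHAG (-7.33). In each of the first 10 the KD IN libraries had 0 reads, as in ULBP3 with 10 reads in KD IP, 0 in KD IN, 5 in NC IP and 34 in NC IN, so these changes are not measured folds. Nor are those of the lowest 10, where NC IN had 0 reads except in ZNF627 (1 read) and YWHAG (2 reads). Of the named 20, edgeR tested MAP1A, CBY1, SMIM10, PNMA8A, HIPK2 and SPHK1, with adjusted p values of 0.12 to 0.16. Without the count filter, edgeR gave ULBP3 an adjusted p of 0.045, VEZT 0.01 and ATP2B1 0.044, and MAGI3 0.077 and DUSP4 0.079.

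Of the 36 authors' calls named for KD 32 were higher, and of the 42 named for NC 39 were lower. Only 9 of the 78 were shared peaks and 69 were not (odds ratio 0.203, Fisher's exact p = 1.2e-07). Peak sets and calls come from the same reads, so both patterns are partly built in by how peaks were chosen. Of 56 of these regions that edgeR tested, all had the same sign and 55 had an unadjusted p under 0.05, and across regions the authors' and the edgeR log2 changes correlated at r = 0.86. The share of the authors' calls in the first 10% of genes was 31.1% (20.8 to 42.9) against 33.1% of other peaks (Fisher's exact adjusted p = 0.9).

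Input signal of the same regions, which follows RNA abundance, differed widely between KD and NC. The largest losses in KD were in genes present in every NC input library and near 0 in KD. NEFM, a neurofilament subunit (chromosome 8, 24918054 to 24918324), had 2160 ± 85.5 CPM (SD, n = 3) in NC and 0.362 ± 0.628 in KD, 1 read, 6380-fold lower (counting interval 1140 to 252000; log2 -12.29, and -14.51 without KD IN replicate 3, which held the read). FLNA, the actin crosslinker filamin A, had 217 ± 37.6 CPM in NC and 0 reads in KD in 1 of its 3 regions, at least 211-fold lower, with log2 -6.69 ± 0.54 and -4.89 ± 0.43 (SE) in the others. HOXC8, a homeobox factor, was at least 158-fold lower, and LIN28B, an RNA-binding regulator of let-7, at least 71.9-fold lower. KRT18, an epithelial keratin from the list of epithelial, fibroblast and kidney-derived markers, was at least 52-fold lower. MAP9, PNMA8A, AKAP12, P3H3 and CCDC8 were at least 52.7-fold to 117-fold lower.

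The highest regions in KD input had no read in NC input at lower depth: SPHK1 (19.5 ± 12.1 CPM, at least 17.4-fold higher), GCLC, of glutathione synthesis (15.2 ± 8.93 CPM, at least 13.3-fold), and SOCS3, a suppressor of cytokine signalling (12.8 ± 10.3 CPM, at least 11.2-fold). PPL, HIVEP3 and KCNAB2 were at least 8.26-fold to 9.74-fold higher, and HIPK1 had 15.6 ± 1.5 CPM against 1 read (40.7-fold, counting interval 6.95 to 1640; log2 5.05, and 7.46 without NC IN replicate 1). The fitted log2 of SPHK1 was 7.73, and 7.13 without KD IN replicate 2. That of SOCS3 was 7.12, and 7.73 without KD IN replicate 1. SYVN1 was at least 5.02-fold higher and lost its call without KD IN replicate 2 (log2 4.59, adjusted p = 0.063). All regions named here were peaks of the NC set. Few NC input reads favour a high IP over input in NC, so these gains may be partly built in. In input, regions in the KD set alone had a median log2 of -0.27 and those in the NC set alone 0.13. Losses in KD-set peaks such as HOXC8 and LIN28B may be favoured likewise, while the FLNA region at 0 reads was an NC-set peak.

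**Figure D2:**
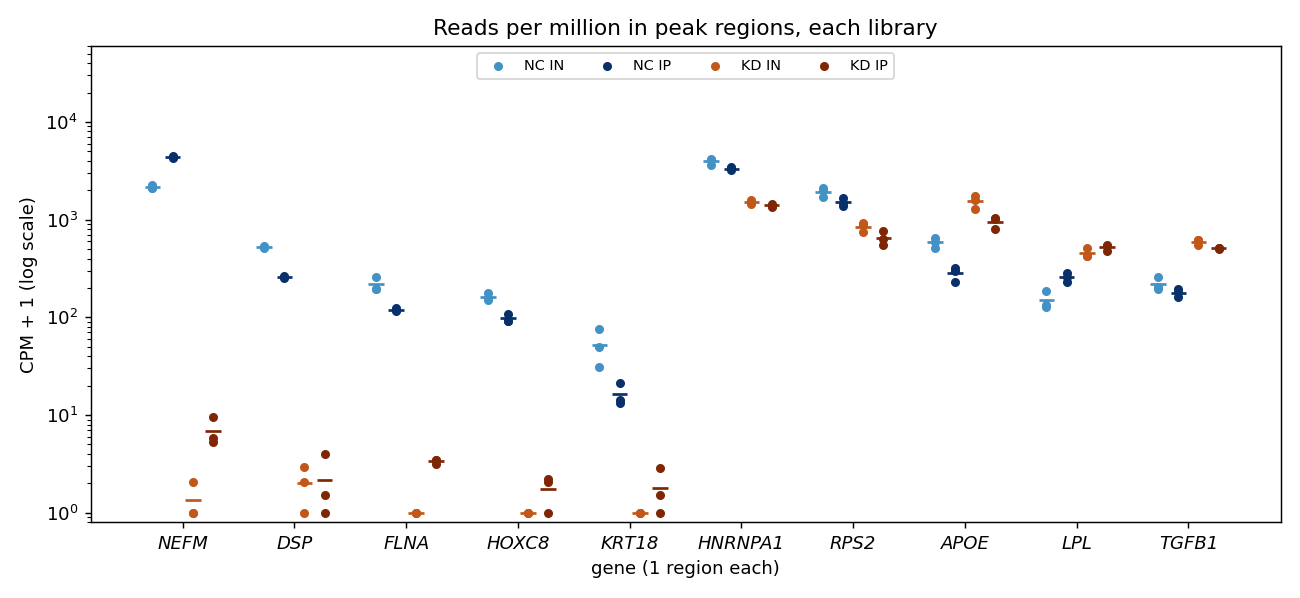
CPM plus 1 on a log axis for 1 region of each gene, with 1 point per library and a bar for the group mean, in NC IN, NC IP, KD IN and KD IP. NEFM, DSP, FLNA, HOXC8 and KRT18 are far lower in the KD libraries, with NEFM at 4.34 to 8.46 CPM in KD IP, HNRNPA1 and RPS2 are lower in KD, and APOE, LPL and TGFB1 are higher.

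Macrophage genes were higher in KD input. Of 22 regions of macrophage differentiation and surface markers, 14 rose and none fell (19 adjusted over the list alone), in 8 of 10 tested genes. They included APOE, a lipid carrier (1540 ± 221 CPM in KD and 585 ± 67.9 in NC, 2.61-fold), the matrix metalloprotease MMP9 (2.29-fold), the integrin subunit ITGB2 (2.09-fold) and the hyaluronan receptor CD44 (2.09-fold). Phagosome and lysosome genes rose in 17 of 30 regions (18 adjusted over the list alone), such as TFEB, a regulator of lysosomal genes (2.44-fold), and the NADPH oxidase subunits CYBA (2.2-fold) and CYBB (1.76-fold). Cholesterol and lipid genes rose in 8 of 15 (8 adjusted over the list alone), such as LPL, lipoprotein lipase (455 ± 51.1 against 149 ± 32.5 CPM, 3.01-fold), SQLE, squalene epoxidase (2.53-fold), and SCD, a fatty acid desaturase (1.57-fold). None of these 3 lists had a lower region. Their median log2 was 0.7, 0.64 and 0.82 over regions, in that order. With 1 region per gene it was 0.63, 0.61 and 0.34.

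Genes of leukocytes in general moved in the same direction: of 8 tested pan-leukocyte genes 6 were higher and 0 lower in KD, with a median log2 of 1 (quartiles 0.77 and 1.17), among them ARHGDIB (1.59 ± 0.12 SE), FERMT3 (1.33 ± 0.11) and LAPTM5 (0.97 ± 0.12). The 10 macrophage genes, 1 region each, had a median of 0.63 against 1.03 for 7 pan-leukocyte genes outside that list (difference -0.4, exact permutation p = 0.19). NEFM and the other transcripts near 0 in KD moved the opposite way in the same libraries.

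Camera called the 3 lists up (adjusted p = 6.3e-05 for macrophage markers, 0.00052 for phagosome and lysosome, 0.0017 for cholesterol and lipid), and all 3 held at adjusted p = 0.047 with an estimated correlation. Cytokines were called up through 8 of 8 regions of TGFB1 (2.73-fold in the region with the smallest p) and CSF1 (4.12-fold; adjusted p = 6.3e-05; 0.051 with an estimated correlation), and the TGFB1 regions lie on both strands. Oxidative stress and ferroptosis genes rose in 6 of 8 regions (adjusted p = 0.023; 0.096 with an estimated correlation), such as the ferritin heavy chain FTH1 (2.2-fold) and the stress regulator NFE2L2 (1.74-fold), while superoxide dismutase SOD1 fell (1.65-fold). Adjusted over the list alone, 8 cytokine and 6 oxidative stress regions rose. In all gene lists overlapping peaks of the NC and KD sets count as separate regions, such as the FTH1 peaks of both sets with the same reads. Counts of regions and camera p values therefore overstate the evidence. Camera called 7 lists in input, against 6 with 1 region per overlapping cluster and 3 with the mean over a gene's regions.

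Many ribosomal protein regions and some splicing factor regions were lower in KD input, but neither list call held with an estimated correlation. Of 18 ribosomal protein regions 14 fell and none rose (14 adjusted over the list alone), including RPS2 (846 ± 90 against 1930 ± 216 CPM, 2.3-fold lower), RPL35 (1.77-fold), RPS14 (1.57-fold) and RPS6 (1.51-fold), with camera adjusted p = 0.00017 and 0.051 with an estimated correlation. Of 41 splicing and hnRNP regions 19 fell and none rose (21 adjusted over the list alone), including SRSF11 (2.64-fold lower), HNRNPA1 (1510 ± 59.6 against 3980 ± 318 CPM, 2.64-fold), HNRNPD (1.79-fold) and HNRNPH1 (1.72-fold), with adjusted p = 6.3e-05 and 0.44 with an estimated correlation. The pan-leukocyte genes rose in the same libraries (median log2 1).

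**Figure D3:**
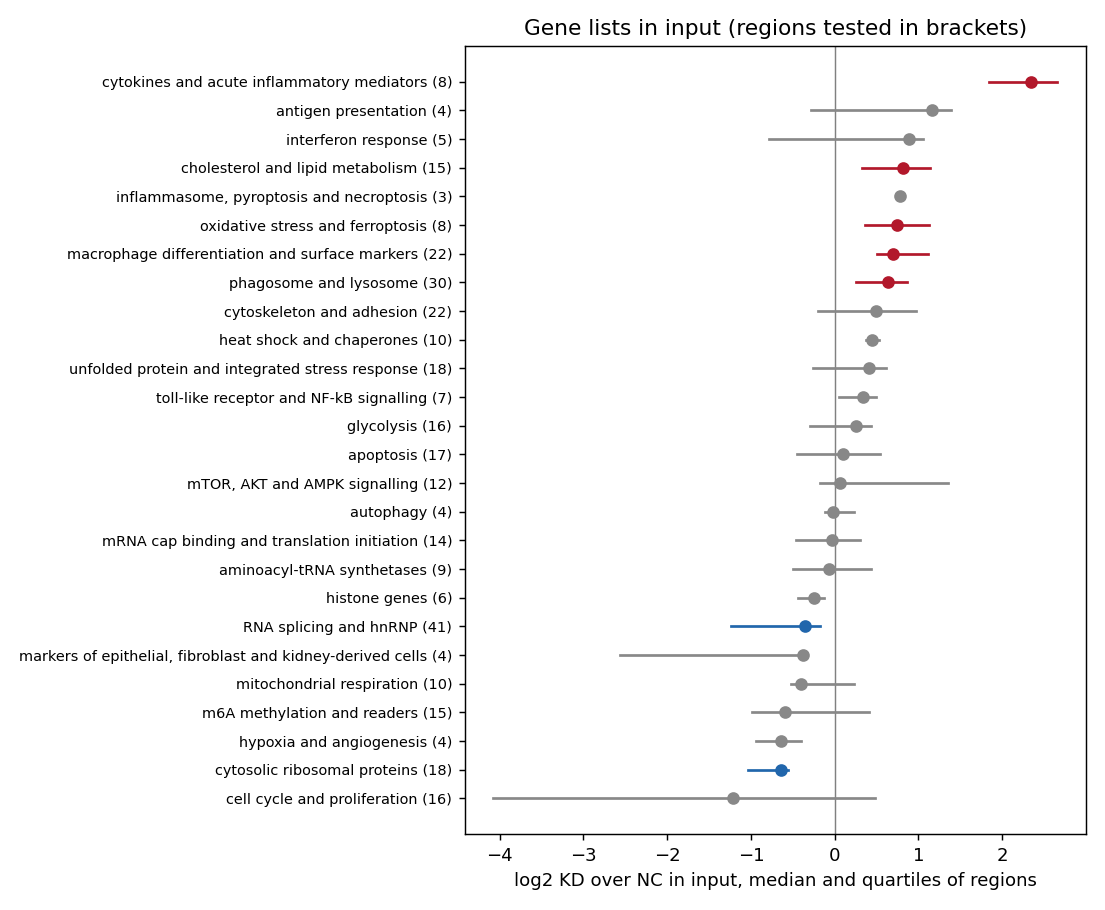
Median (point) and quartiles (line) of log2 KD over NC in input over the tested regions of each gene list with at least 3, with the number of regions in brackets. Red and blue mark the 5 lists called up and the 2 called down by camera with the preset correlation, and grey the others; macrophage markers had a median of 0.7 and ribosomal proteins -0.64.

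In all, edgeR called 2035 of 5113 input regions, 917 higher and 1118 lower in KD (1039 and 1010 with library size alone, so which direction had more calls depends on the scaling), in 1154 of 2623 genes, and 1868 of them had KD and NC libraries that did not overlap. Called or not, 2290 regions had no such overlap (44.8% of all against 10% by chance). DESeq2 called 2523. In the IP libraries 2097 regions differed, 1067 higher and 1030 lower. Input and IP changes correlated at r = 0.75 across regions (Spearman's rho 0.74), with 677 regions higher in both, 790 lower in both and 3 in opposite directions.

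**Figure D4:**
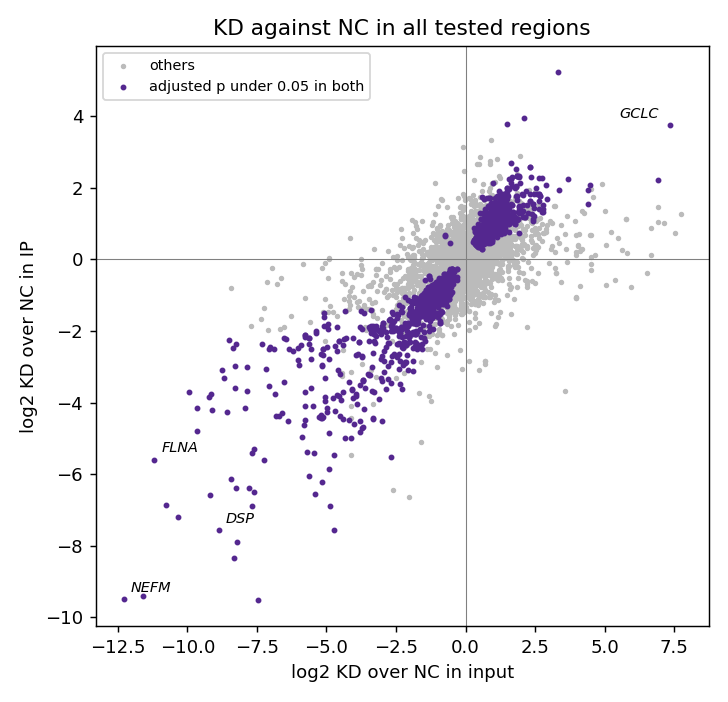
Log2 KD over NC of each of the 5113 tested regions in input (x axis) and in IP (y axis), with regions called in both in purple. NEFM, FLNA and DSP lie among the lowest on both axes.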

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

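The tests of the transcripts that KD lacks, with their bounds, were chosen only after the result was seen, while the tests of selection, input coverage and region length were written before. In 37 of the authors' 78 calls, 18 higher and 19 lower in KD, every KD replicate leaned to one side of IP over input and every NC replicate to the opposite. Of these, 16 were removed by the count filter, and the 11 given here are those of the 16 among the regions named in the report. The difference in log2 IP over input, KD minus NC, was 5.65 in ULBP3, 5.45 in AK3, 5.32 in ISG20L2 and 4.43 in MAGI3, and -5.25 in YWHAG, -5.79 in VEZT, -6.0 in ZNF627, -5.23 in SEMA3D, -4.96 in CNP, -4.5 in DUSP4 and -4.68 in ATP2B1. With groups of 0 to 2 reads the pseudocount of 0.5 CPM sets the size of these values, so they are not measured folds. These 11 regions held 30 to 94 reads over all libraries, 9 of the 11 had an input group at 0 reads, and 4 were higher and 7 lower. Without the count filter edgeR called 9 of the 11 (adjusted p = 0.01 to 0.049), but not MAGI3 (0.077) or DUSP4 (0.079). The cause was not tested.

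NEFM, DSP, FLNA and other transcripts were abundant in every NC library and far lower in every KD library: of 1062 genes with at least 50 CPM in input, 19 were lower beyond 8-fold in KD and 0 higher, a count that leaves out weaker regions higher in KD such as SPHK1 (19.5 CPM). NC libraries without THP-1 RNA are argued against, since pan-leukocyte genes had a median log2 of 1 and each at least 9.41 CPM in NC. RNA of HEK293-like cells in NC might give the pattern: 16 of 25 tested genes of a HEK293 list were lower (odds ratio 5.42), but that list was written after many of its genes had been seen. Without the 12 seen genes, 4 of 13 were lower (odds ratio 1.36, 0.304 to 4.88, Fisher's exact p = 0.54). Every seen gene left out was a lower one, which by itself lowers the odds ratio, so the test cannot decide. An effect of the knockdown and a difference between cell stocks were not tested and stay open. Of the 25 genes 15 had reads above the floor of 3 counts in KD input, but with unlike amounts. NEFM had 5 reads against 14330 in NC input and NEFL 6 against 1645, while TCEAL9 had 2922 against 5854.

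Peaks named for 1 group leaned to that group in enrichment change, with a gap between medians of 0.93. Noise selected when peaks are called in each group may account for much of it: the gap was 2.01 in regions with 52 to 293 reads, 0.75 with 294 to 1220 and 0.25 above, 12.4% of that in the lowest group.

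The first 10% of genes was more enriched in IP. Low input coverage at the 5 prime end might raise the ratio there: the gap to the rest was -0.03, 0.28 and 0.21 from the lowest to the highest input per kb in NC and 0.03, 0.28 and 0.21 in KD, which cannot tell. Region length is argued against, as the gap was at least 0.48 in each group of lengths. An m7G cap carried by every mRNA was not tested.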

How the results depend on the processing

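Regions called in both groups and 1 region per overlapping cluster were tests chosen only after results were seen. For enrichment change the count of 0 became 12 with DESeq2, 45 with no filter, 16 (15 higher, 1 lower) with a block for IP and input of a sample, 40 in the upper 50% of peaks by the authors' fold, 610 at unadjusted p and 2097 in IP libraries alone; it stayed 0 with library size alone, at least 50 reads, a block by replicate number, other thresholds, genes in place of peaks and both added sets. Leaving out 1 library gave 0 to 1. Same-number IP and input libraries correlated at -0.02 to 0.07 after group means were removed; each KD library correlated best with its own number (0.05 to 0.06, others at most 0), but in NC only number 1 did, so the block is a hint from the data and the pairing is not shown. The list count for enrichment change fell from 1 to 0 with an estimated correlation, fry, 1 region per cluster or gene means, and was 0 to 2 in leave-outs; for input it went from 7 to 3, 20, 6 and 3, and stayed 7 in leave-outs. Input calls were 1934 to 2091 in leave-outs and 1240 in regions called in both groups, and IP over input was 1504 in NC and 1399 in KD with 1 region per cluster, and 1960 to 2623 and 1960 to 2495 in leave-outs. Shared peaks were 29.2% with 50% reciprocal overlap. They were 20.4% with both sets cut to the upper 50% by fold, which lowers the share by itself. The first 10% of genes held 35.8% of bases, 31.5% of upper-fold peaks and 29.7% of narrow peaks. In an alternative chosen after results were seen, it held 33.3% of peaks of genes with all of 2 or more peaks on 1 strand. Over leave-outs, named genes were weaker in 87 cases, stronger in 12, reversed in 12 and otherwise the same. Reversals were in genes whose log2 KD over NC in input was small: GABARAPL1 (0.05 with library size alone, 0.03 with no filter, -0.36 to 0.27 in leave-outs), H1-10 (-0.3 to 0.18), IRAK1 (-0.02 to 0.21), TIAL1 (-0.41 to 0.12), CCL5 (-0.64 to 0.37) and COL3A1 (-0.43 to 0.09). Peak calls per library and normalization to METTL1 were not run, for want of a call per library and of a METTL1 region.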

Other observations

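The tests with the pan-leukocyte, HEK293, fibroblast and other marker lists, and of macrophage against pan-leukocyte genes, were chosen only after the result was seen. Proliferation genes were lower in KD input in 5 of 10 tested genes (7 regions) and higher in 1, CCND1, whose 4 higher regions lie on both strands. Of 2598 genes outside the HEK293 list, 24.7% were lower in KD input by 1 region per gene. The pan-leukocyte genes rose in the same libraries (median log2 1). TOP2A, a topoisomerase of dividing cells, was 3.61-fold lower (112 ± 7.93 against 410 ± 64.5 CPM, SD, n = 3), and MCM3, of the replication helicase, 5.19-fold lower. Cytoskeletal ACTB (1.72-fold), VIM (2.12-fold) and TPM4 (2.77-fold) were higher, as were the chemokine CCL22 (3.55-fold), the invariant chain CD74 (2.64-fold) and the urokinase PLAU (3.61-fold). Of the same lists, FLNA and HLA-F were lower, HLA-F 16.2-fold (counting interval 5.18 to 81.6; log2 -3.91, and -7.49 and -3.31 without KD IN replicates 1 and 2), and the cytoskeleton list had 7 regions higher and 4 lower. LDHB was 2.31-fold and PFKM 8.55-fold lower while PKM was 1.48-fold higher (PFKM log2 -3.05, and -2.42 without KD IN replicate 1), and the stress genes ATF4 (1.59-fold) and DDIT4 (2.04-fold) were lower while PPP1R15A (1.63-fold) was higher. Each passed the threshold in edgeR. Camera called none of the lists of cell cycle, cytoskeleton, antigen presentation, glycolysis and stress response genes, and the chemokine and complement lists, with 2 and 1 tested regions, were not tested by it.

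In the IP libraries large losses in KD were those of IRS4, an insulin receptor substrate (at least 124-fold lower, 68.1 ± 9.2 CPM against 0), NEFM (733-fold), BEX2 (367-fold), TUBB2B (288-fold, counting interval 51.2 to 11400; log2 -7.57, and -9.07 without KD IP replicate 2) and NEFL (251-fold), and the largest gains SNTB1 (16.1-fold), AP1S2 (14.2-fold), GCLC (14.1-fold; log2 3.76, and 4.77 without NC IP replicate 1) and the receptor FLT1 (10.5-fold). PDGFA was 6.61-fold higher. Camera called 8 lists in IP, 6 up and 2 down; ribosomal proteins (adjusted p = 1.5e-07), macrophage markers (2.1e-05), phagosome and lysosome (0.00014) and cholesterol and lipid (0.0038) held with an estimated correlation (0.034, 0.034, 0.034 and 0.045).

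Markers of other cell types were checked in input. KRT18 of the epithelial, fibroblast and kidney-derived list was at least 52-fold lower in KD and COL3A1 did not pass (log2 -0.26, adjusted p = 0.66 in edgeR). Of 4 tested fibroblast genes 2 were lower (odds ratio 3, Fisher's exact p = 0.26), and 1 of 1 surface epithelium gene; erythroid, lymphoid and hepatocyte lists had 0 tested genes. Of the 8 pan-leukocyte genes SPI1 and CYBB are in other fixed lists too, and the HEK293 list held 2 genes higher in KD, NEFH (log2 1.12) and HMGA2 (2.49).

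In 10 splits of the 6 libraries of a comparison the real grouping gave 2035 input regions, against at most 2 in any other, 2097 in IP against 0, and 2389 and 2296 for IP over input in NC and KD against 0, so 1 split, the real one, gave as many. For enrichment change the real value was 0 and the highest other 0, so 10 splits gave as many. These 10 splits are too few to judge a result by.

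The higher macrophage, phagosome and lipid transcripts in KD might follow a larger share of THP-1 RNA in KD libraries, since pan-leukocyte genes were higher by a median of 1. Whether the lower ribosomal, splicing and proliferation transcripts follow the same difference in share was not tested. Macrophage genes had a median 0.4 lower than the pan-leukocyte genes (difference -0.4, exact permutation p = 0.19), so a shift of macrophage genes beyond other leukocyte genes was not seen. The HEK293 test (odds ratio 1.36), which left out only lower genes, cannot tell whether NC libraries hold RNA of other cells.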
